A study of Mus musculus with 8 samples.

How the data were processed

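The 8 samples are of primary mouse ependymal cultures, 4 titled untreated and 4 titled EGF (20 ng/ml), each measured on its own array with biotin-labelled RNA. Samples were grouped by their titles. The source names of the same samples give DMSO and MLN4924 in place of untreated and EGF, and nothing in the sources used here settles the conflict. The labels number the replicates 1 to 4 in each group and do not say that they came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. No pair of arrays was identical: Pearson's r across clusters was 0.996 to 0.997 within the untreated group and 0.994 to 0.995 within the EGF group.

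The authors deposited 1 table of log2 signals per transcript cluster of a whole-transcript mouse array. That the scale is log2 was taken from the range of the values and from the header of the second deposited table; the base is not stated for the first table itself. RMA, affy and limma are named in the submitters' processing notes, without versions, roles or order. The column medians of the deposited log2 values were 4.59, 4.59, 4.56 and 4.60 (untreated) and 4.77, 4.71, 4.82 and 4.79 (EGF), so the arrays are not on 1 common median, and how they were centred stays unknown. The second deposited table gives, per the file headers, the authors' log2 group averages, a p-value and a false discovery rate for ctrl against gf; all its rows have an absolute difference of at least 1 and a p-value under 0.05. The array's genome build is not given in the sources used here, so no coordinates are printed. No scanner files, detection calls or control probe sets were used here.

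Cluster names came from the platform annotation, updated through a RefSeq gene table of assembly GRCm38.p6, used for names only. Of 65956 clusters 30638 had 1 gene symbol, 2176 had several and 33142 had none; 654 clusters with several symbols resolved to 1 gene and 1522 were left out. Of 31292 clusters with 1 gene, 31290 matched the RefSeq table. For a gene with several clusters (439 genes) the one with the highest mean over all arrays was used, which gave 30738 genes. Among the named genes Nrg1 and Rpl27 had 2 clusters, of the same sign. Foxj1 and Pdgfra, fixed in advance, have no cluster of their own and are not analysed here, and a further item of the fixed set is not reported here. No filter on dim clusters and no further normalization was applied. Signals close to the array medians lie where most clusters lie, and folds that end there can be understated.

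The deposited values were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Of these calls, those of at least 2-fold (absolute log2 fold change of at least 1) were counted apart. The 33 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists, and beside it with an estimated correlation, with fry and against 10000 random lists matched on level in 20 bins. Member counts use the adjustment over all genes, and that over the list alone is given beside them. Genes are named by a rule fixed in advance: the 12 largest rises and 12 largest falls among genes that passed, did not overlap between groups and reached a mean of 6 in the higher group, leaving out clone and predicted names; up to 4 members of each list with the largest absolute change among those that passed; and a fixed set that includes Mcidas, Gmnc, Egfr, Numb, Numbl, Nes, Gfap, S100b, Mki67, Dcx, Olig2, Dusp6, Spry4, Etv4, Cdkn1a and Nqo1.

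The steps were tested on simulated data for the EGF versus untreated comparison over 30738 genes. Of 67 genes changed by 0.5 on the log2 scale 28 were recovered (41.8%), of 67 changed by 1, 62 (92.5%), and of 66 changed by 2, 65 (98.5%), with 9 false calls. Of 200 unshifted lists of 25 genes 8 had p under 0.05. Genes were simulated as independent of each other, so this does not test the list p-values where genes move together. Only 200 genes were changed and the others had no shift, unlike the arrays, where 60.3% of genes were called. The shares recovered and the false calls therefore do not carry over to the counts below. Named alternatives were a further quantile normalization, centring on the median, cyclic loess, a filter on dim clusters, the mean of a gene's clusters, array weights, eBayes with trend and robust, a replicate block, leaving out each array, every named cluster tested, an adjusted p under 0.01, treat at 1.5-fold and the tests of lists above. The alternative on suffixes of probe set names does not apply to this array, and the planned test of RNA integrity on 3' and 5' control probe sets was not run, since those probe sets are not among the values used here. Intervals of list medians came from 10000 bootstrap draws of members. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.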

Results

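RNA was measured in 8 samples of primary mouse cultures grown from radial glia, the progenitors from which ependymal cells, the ciliated lining of the brain ventricles, are derived. By their titles, 4 samples are of cultures kept in differentiation medium alone and 4 of cultures given 20 ng/ml epidermal growth factor (EGF) from the start of differentiation, each for 2 weeks. The labels conflict: the source names give the solvent DMSO for the untreated samples and MLN4924, an inhibitor of the enzyme that attaches NEDD8 to cullin ubiquitin ligases, for the EGF samples. Groups follow the titles, descriptions and treatment protocol, and "EGF" below means the arrays so titled. Each array gave 65956 transcript clusters on a log2 scale, with medians of 4.59, 4.59, 4.56 and 4.60 in untreated replicates 1 to 4 and 4.77, 4.71, 4.82 and 4.79 in EGF replicates 1 to 4. The number of arrays, 4 per group, limits the precision. The design asks what EGF during differentiation does to the expression of these cultures.

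Genes of motile cilia and the regulators of multiciliated cells were among the largest falls with EGF, and Fbln2, Vegfa and Slc2a3 were among the largest rises. Fam216b fell from 14.64 ± 0.18 to 6.06 ± 0.28 (log2 signal, mean ± SD, n = 4), Deup1, a protein of the structures that multiply centrioles, fell by 8.34 ± 0.09 (log2 fold change ± SE), and the radial spoke gene Rsph4a fell by 7.62 ± 0.19. Spata18, Ch25h, Ak7, Ppp1r32, Rsph1, Dynlrb2, Cfap206, Steap4 and Dnajb13 completed the 12 largest falls. Fbln2, an extracellular matrix gene, rose from 6.29 ± 0.47 to 13.65 ± 0.07 (n = 4), the angiogenic factor gene Vegfa rose by 6.65 ± 0.17, and the glucose transporter gene Slc2a3 rose by 5.71 ± 0.06. Cacng5, Ntsr2, Liph, Slc6a11, Nxph4, Dhh, Apln, Grm3 and Fgf11 completed the 12 largest rises. Each of these 24 genes had an adjusted p of 9.9e-09 or less in limma, and all 4 EGF arrays lay on one side of all 4 untreated arrays.

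Of 30738 genes tested with limma, 18549 changed (60.3%), of which 12198 rose and 6351 fell. At least 2-fold, 4203 genes changed, 1921 up and 2282 down. The median log2 fold change of all genes was 0.17 (0.0083, -0.020 and -0.011 after the 3 scalings below), and the split of calls moved with the scaling: 65.8% of the changed genes rose with the deposited values, 48.8% after a further quantile normalization, 40.2% after centring each array on its median and 43.0% after cyclic loess. Of the genes changed at least 2-fold, 45.7% rose with the deposited values and 32.5% after median centring. Changes near 0.17 therefore have no settled direction. The groups did not overlap in 16590 genes (54.0%), against 2.86% by chance. The first principal component held 90.9% of the variance and parted the groups (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow); with genes scaled to unit variance it held 59.6%, with the same p.

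**Figure D1:**
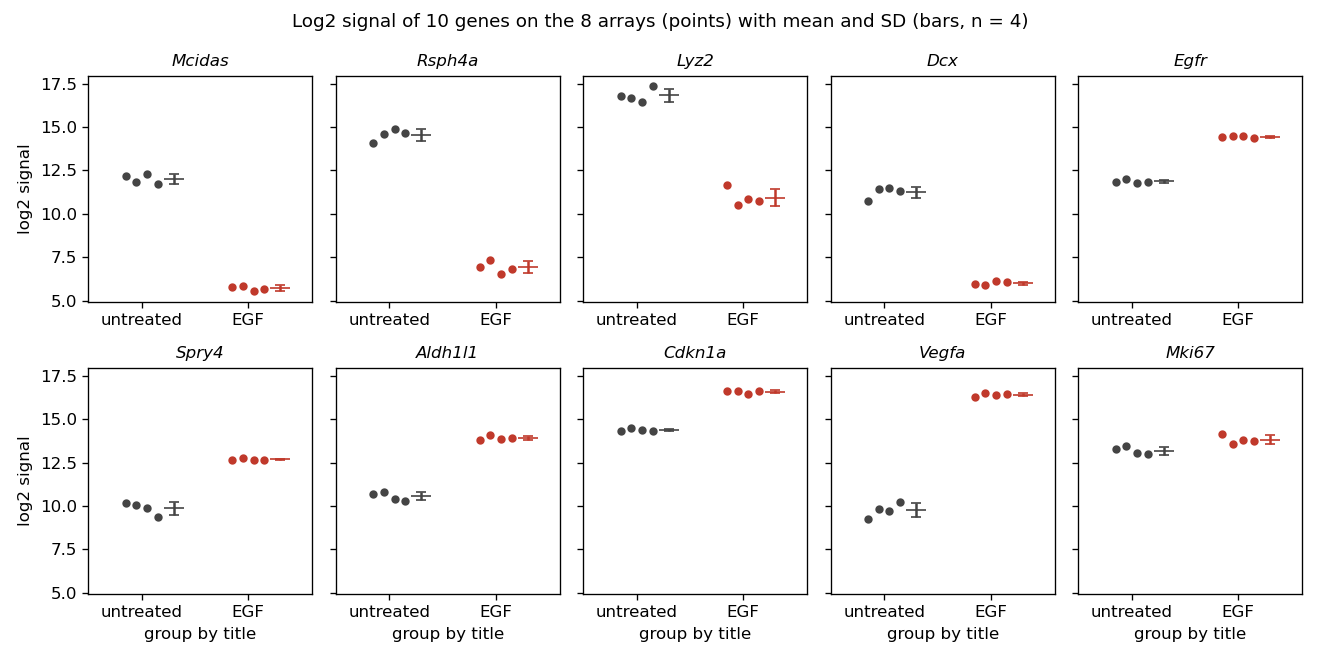
Log2 signal (vertical axis) of 10 genes on each array, grouped by title on the horizontal axis; points are the 4 arrays of a group, and bars give the mean ± SD. Rsph4a, Lyz2 and Dcx lie lower and Egfr, Vegfa and Cdkn1a higher on all 4 EGF arrays than on any untreated array; Mki67 differs by 0.62.

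The genes that build motile cilia fell nearly as a whole. Of 82 measured genes of the motile cilia axoneme, 81 fell, 0 rose and 1 did not pass, with a median log2 fold change of -4.20; the counts were equal when adjusted over the list alone. Rsph4a, Ak7, Rsph1 and Cfap206 showed falls of over 7 on the log2 scale. The list's shift had a camera adjusted p = 2.8e-52 with the preset correlation and adjusted p = 0.215 with an estimated correlation. Of 27 intraflagellar transport genes, which carry cargo along cilia, 25 fell and 2 did not pass (median -1.59), among them Ift22 (-3.54 ± 0.09 SE) and Ift88 (-2.81 ± 0.10); adjusted over the list alone, 25 fell and 1 rose. That list had adjusted p = 1.3e-16, and adjusted p = 0.215 with an estimated correlation.

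Regulators of multiciliation were lower too. Of 19 measured members 18 fell and 1 rose (median -1.82), with the same counts adjusted over the list alone: Mcidas, which starts the multiciliated programme with Gmnc, fell from 12.02 ± 0.27 to 5.72 ± 0.15 (n = 4), Gmnc by 2.21 ± 0.17 (SE), Myb by 6.20 ± 0.12 and Cdc20b by 5.90 ± 0.12. The list had adjusted p = 1.2e-12, and adjusted p = 0.215 with an estimated correlation. Of 24 mature ependymal markers 22 fell, 1 rose and 1 did not pass (median -1.80, adjusted p = 6.5e-16; adjusted p = 0.215 with an estimated correlation), with the same counts adjusted over the list alone. Odf3b fell by 6.59 ± 0.25 and S100b by 2.23 ± 0.10. Foxj1 is not reported, because its cluster is shared with another gene. The markers of microglia, immune cells of the brain, moved with these lists: 17 of 18 fell, 0 rose and 1 did not pass (median -2.79), also adjusted over the list alone.

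Targets and feedback inhibitors of ERK signalling, which lies downstream of the EGF receptor, were higher with EGF. Of 27 measured, 22 rose, 4 fell and 1 did not pass (median 1.73), with the same counts adjusted over the list alone. The immediate early genes Egr1 and Fos rose by 3.65 ± 0.10 and 3.38 ± 0.12 (log2 ± SE), and the inhibitors Spry2, Spry4 and Dusp6 by 3.25 ± 0.11, 2.83 ± 0.15 and 1.83 ± 0.15. The transcription factor gene Etv4 rose by 2.23 ± 0.07. The list had adjusted p = 1.2e-05, and adjusted p = 0.215 with an estimated correlation. Egfr itself rose from 11.87 ± 0.09 to 14.44 ± 0.07 (n = 4). In the list of EGF receptor family genes and ligands, 9 of 19 rose, 7 fell and 3 did not pass, with the same counts adjusted over the list alone; Nrg1 fell by 3.30 ± 0.10, while Hbegf rose by 1.34 ± 0.14 and Lrig1 by 1.26 ± 0.07. The median of that list was 0.14 and its camera direction was down, with adjusted p = 0.854; the direction turned under other scalings.

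Genes of EGF receptor trafficking and turnover went both ways: 8 of 31 rose, 12 fell and 11 did not pass (median -0.06), with the same counts adjusted over the list alone; 18 fell after centring each array (median -0.25, adjusted p = 0.0291) and 16 after cyclic loess (median -0.20). Dab2, an endocytic adaptor, fell by 1.86 ± 0.08 and Rab11b by 1.35 ± 0.08. Numb, an endocytic adaptor known for its unequal inheritance in dividing progenitors, fell by 0.48 ± 0.07, and its relative Numbl rose by 0.67 ± 0.08. The list had adjusted p = 0.0333, and adjusted p = 0.479 with an estimated correlation; the call ended under a further quantile normalization (adjusted p = 0.149), cyclic loess (adjusted p = 0.0798), with brighter clusters alone (adjusted p = 0.251), against random lists (adjusted p = 0.353) and without EGF replicate 1 (adjusted p = 0.0512).

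Radial glia and stem cell genes moved in both directions. Of 30 members 16 rose, 10 fell and 4 did not pass (median 0.38, adjusted p = 0.663), and 16 rose and 11 fell adjusted over the list alone. Under 3 other scalings the median was 0.24, 0.19 and 0.26. Fabp5 rose by 2.84 ± 0.07, Slc1a2 by 2.37 ± 0.07 and Hes1, a Notch target, by 2.11 ± 0.09, while Id4 fell by 4.22 ± 0.13 and Nes by 1.20 ± 0.13. Among activated stem and transit amplifying cell genes, 6 of 18 rose, 10 fell and 2 did not pass (median -0.36, adjusted p = 0.0969), with the same counts adjusted over the list alone. The interneuron lineage factors Dlx2, Dlx1 and Dlx5 fell (-3.99 ± 0.24, -3.69 ± 0.21 and -3.50 ± 0.20), and Egfr was among the members that rose. Olig2 rose by 0.89 ± 0.11.

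Cell cycle genes did not move as 1 group. Of 28 G1/S and DNA replication genes 16 fell, 3 rose and 9 did not pass (median -0.32), with the same counts adjusted over the list alone. After quantile normalization 16 fell (median -0.338), after centring 20 (-0.505) and after cyclic loess 18 (-0.446). Tyms fell by 1.43 ± 0.09 and Mcm5 by 0.92 ± 0.15. That list had adjusted p = 5.7e-04, and adjusted p = 0.536 with an estimated correlation; against random lists its adjusted p was 0.0543. Of 28 G2/M and mitosis genes 18 rose, 2 fell and 8 did not pass (median 0.48), with the same counts adjusted over the list alone. Hmmr rose by 1.47 ± 0.16, Aurkb by 1.13 ± 0.14 and Mki67, a proliferation marker, by 0.62 ± 0.14, while Ckap2l fell by 1.09 ± 0.12. The G2/M list had adjusted p = 0.0894 with the deposited values and passed after each of 3 other scalings (adjusted p = 0.00725, 0.0131 and 0.00592). Fewer of its members rose under those scalings (16, 13 and 14), and its median was lower (0.38, 0.29 and 0.36).

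Astrocyte markers were mostly higher: 17 of 23 rose and 6 fell (median 0.48), with the same counts adjusted over the list alone. Ntsr2 rose by 6.18 ± 0.11, Aldh1l1 from 10.56 ± 0.24 to 13.92 ± 0.13 (n = 4), Cldn10 by 3.11 ± 0.11 and Agt by 2.95 ± 0.19, while S100b fell by 2.23 ± 0.10 and Gfap, the astrocyte filament gene, by 0.48 ± 0.08; the largest of the 6 falls, of Itih3 (-2.64 ± 0.08), and those of Aqp4 (-1.31 ± 0.06), Clu (-1.20 ± 0.07) and Mlc1 (-1.06 ± 0.06) are named after their values were seen. The list had adjusted p = 0.0980 with the deposited values and passed after 3 other scalings (adjusted p = 0.0447, 0.0131 and 0.0111). Under those scalings 15, 14 and 15 members rose. Of 25 reactive astrocyte genes 5 rose, 16 fell and 4 did not pass (5 and 17 adjusted over the list alone; median -0.60, adjusted p = 1.2e-05; adjusted p = 0.256 with an estimated correlation), with Cp and Steap4 lower and Ptgs2, an inflammatory enzyme gene, higher by 4.12 ± 0.17; 17 of 18 microglial markers fell beside them.

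Markers of several other cell types were lower. The microglial list had adjusted p = 3.5e-12, and adjusted p = 0.215 with an estimated correlation; Lyz2 fell by 5.88 ± 0.25, Fcer1g by 4.52 ± 0.29, C1qb by 4.42 ± 0.29 and Itgam by 4.31 ± 0.28. Of 24 neuroblast and neuron genes 19 fell, 2 rose and 3 did not pass (median -0.93, adjusted p = 1.9e-08; adjusted p = 0.253 with an estimated correlation), and Dcx, Stmn2 and Tubb3 fell (-5.23 ± 0.14, -4.81 ± 0.09 and -4.36 ± 0.16). Of 15 choroid plexus genes 8 fell, 1 rose and 6 did not pass (median -0.60, adjusted p = 5.0e-04; adjusted p = 0.256 with an estimated correlation), with Kcnj13 (-4.13 ± 0.19) and Folr1 (-2.44 ± 0.09) lower; with brighter clusters alone the median was -1.06. Counts adjusted over the list alone were equal for these 3 lists.

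Lists of the remaining cell types held members that rose and members that fell. Of 17 oligodendrocyte genes 3 rose, 8 fell and 6 did not pass (median -0.10, adjusted p = 0.0183; adjusted p = 0.265 with an estimated correlation), with Tspan2 (-2.67 ± 0.15) lower; the call ended with brighter clusters alone (median -0.34, adjusted p = 0.0686) and against random lists (adjusted p = 0.0691). Of 17 oligodendrocyte precursor genes 9 rose, 4 fell and 4 did not pass (median 0.21, adjusted p = 0.543). Their median was 0.116, 0.0225 and 0.040 under 3 other scalings, and Bcan rose by 1.92 ± 0.07. Of 21 fibroblast and mural cell genes 5 rose, 10 fell and 6 did not pass (median -0.09, adjusted p = 0.0333; adjusted p = 0.536 with an estimated correlation), with Postn (-3.77 ± 0.14) and Col1a1 (-2.87 ± 0.29) lower and Igfbp4, the member with the largest change, higher by 3.90 ± 0.12. Its call ended after centring (adjusted p = 0.0614), cyclic loess (adjusted p = 0.0565), with brighter clusters alone (median -1.11, adjusted p = 0.0938), with fry (adjusted p = 0.0550) and without EGF replicate 2 (adjusted p = 0.0573). Of 14 endothelial genes 4 rose, 4 fell and 6 did not pass (median 0.12, mean -0.43, adjusted p = 0.396), and the median turned to -0.081, -0.068 and -0.079 under 3 other scalings and to -0.59 with brighter clusters alone; Slco1a4 fell by 5.21 ± 0.17 and Flt1 rose by 1.91 ± 0.06. Among the 4 endothelial genes that rose, Cldn5 (3.32 untreated, 3.84 EGF) and Tie1 (4.26 and 4.44) lay below all array medians, so their rises are of dim signals. Counts adjusted over the list alone were equal for these 4 lists.

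Glycolysis and p53 target genes rose. Of 17 glycolysis genes 16 rose and 1 fell (median 2.01, adjusted p = 1.3e-07; adjusted p = 0.232 with an estimated correlation): Eno2 rose by 3.46 ± 0.09, Hk2 by 3.39 ± 0.11 and Slc16a3, a lactate transporter gene, by 2.95 ± 0.13. Of 18 p53 target genes 15 rose, 1 fell and 2 did not pass (median 1.28, adjusted p = 1.1e-04; adjusted p = 0.306 with an estimated correlation); Eda2r rose by 3.62 ± 0.10, and the cell cycle inhibitor gene Cdkn1a from 14.38 ± 0.07 to 16.57 ± 0.09 (n = 4). All 14 measured ribosomal protein genes rose (median 0.81, adjusted p = 7.4e-06, and adjusted p = 0.215 with an estimated correlation), also under the 3 other scalings in median. That list was fixed in advance as the control, and it passed too, which limits what a call at the preset correlation can mean. Processed copies of these genes make their signals uncertain. Counts adjusted over the list alone were equal for these 3 lists.

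Other stress and metabolic lists went both ways. Of 18 NRF2 targets, genes of the oxidative stress response, 8 rose, 7 fell and 3 did not pass, and 9 rose and 7 fell adjusted over the list alone (median 0.22, camera direction down, adjusted p = 0.877). Me1 and Ephx1 rose by 1.83 ± 0.08 and 1.78 ± 0.07, while Pgd fell by 1.32 ± 0.08 and Nqo1 by 0.69 ± 0.14. Of 19 apoptosis and stress genes 7 rose, 6 fell and 6 did not pass (median -0.01, mean 0.34, adjusted p = 0.544); Ddit4 rose by 5.42 ± 0.12 and Shmt2 by 2.41 ± 0.08, and Hsph1 fell by 2.10 ± 0.07. Of 18 cholesterol synthesis genes 12 rose, 4 fell and 2 did not pass (median 0.59, adjusted p = 0.135, passing after 3 other scalings with adjusted p = 0.0185, 0.0286 and 0.0191); Insig1 rose by 2.28 ± 0.12 and Sqle fell by 1.27 ± 0.10. Counts adjusted over the list alone were equal for the last 2 lists.

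Notch pathway genes were higher and BMP, matrix and interferon genes lower on balance. Of 23 Notch genes 14 rose, 4 fell and 5 did not pass (15 and 4 adjusted over the list alone). The list's median was 0.60, with adjusted p = 0.0195, and adjusted p = 0.306 with an estimated correlation. Nrarp (3.29 ± 0.09), Hes1 (2.11 ± 0.09) and Notch3 (2.06 ± 0.08) rose most. Of 22 BMP and Id genes 7 rose, 9 fell and 6 did not pass (7 and 10 adjusted over the list alone; median -0.17, adjusted p = 0.0412; adjusted p = 0.265 with an estimated correlation), where Bmp6 fell by 4.12 ± 0.11 and Bmpr1b rose by 3.24 ± 0.12. The BMP call ended under 3 scalings (adjusted p = 0.0625, 0.0819 and 0.0798), with brighter clusters alone (adjusted p = 0.193) and without EGF replicate 1 (adjusted p = 0.0565) or 4 (adjusted p = 0.0541). Of 31 collagen and basement membrane genes 9 rose, 19 fell and 3 did not pass (10 and 19 adjusted over the list alone; median -0.67, adjusted p = 6.3e-04; adjusted p = 0.479 with an estimated correlation), and Thbs1 fell by 6.09 ± 0.16. Of 26 interferon response genes 18 fell, 1 rose and 7 did not pass (20 and 1 adjusted over the list alone; median -1.40, adjusted p = 3.6e-08; adjusted p = 0.435 with an estimated correlation), and Bst2 fell by 3.50 ± 0.36; the microglial markers fell beside them (17 of 18, median -2.79).

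Of 32 junction and adhesion genes 11 rose, 16 fell and 5 did not pass (median -0.09, adjusted p = 0.00830; adjusted p = 0.324 with an estimated correlation), with the polarity genes Pard6b (-2.99 ± 0.12) and Crb2 (-2.71 ± 0.14) lower and the claudin gene Cldn10 (3.11 ± 0.11) higher; with brighter clusters alone the median was -0.51, and the call ended after cyclic loess (adjusted p = 0.0503) and against random lists (adjusted p = 0.0543). Of 10 Hedgehog genes 4 rose, 4 fell and 2 did not pass (4 and 5 adjusted over the list alone). The median was 0.05 and the mean -0.13 (adjusted p = 0.526), and the median was 0.0026, -0.1425 and -0.092 under 3 other scalings. Cdon fell by 2.04 ± 0.08. Of 12 Wnt genes 3 rose, 2 fell and 7 did not pass (median 0.07, mean -0.05, adjusted p = 0.863). Their median turned to -0.079, -0.121 and -0.101 under 3 other scalings. Sfrp1, a secreted Wnt antagonist, fell by 4.06 ± 0.12 and Dkk3 rose by 2.82 ± 0.18. Counts adjusted over the list alone were equal for the junction and Wnt lists. Of the 33 lists, 21 passed with the preset correlation and 0 with an estimated one (adjusted p from 0.215 to 0.899), 30 passed with fry and 20 against random lists. Because fry asks only whether a list's genes move one way, its calls do not set a list apart from other genes.

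**Figure D2:**
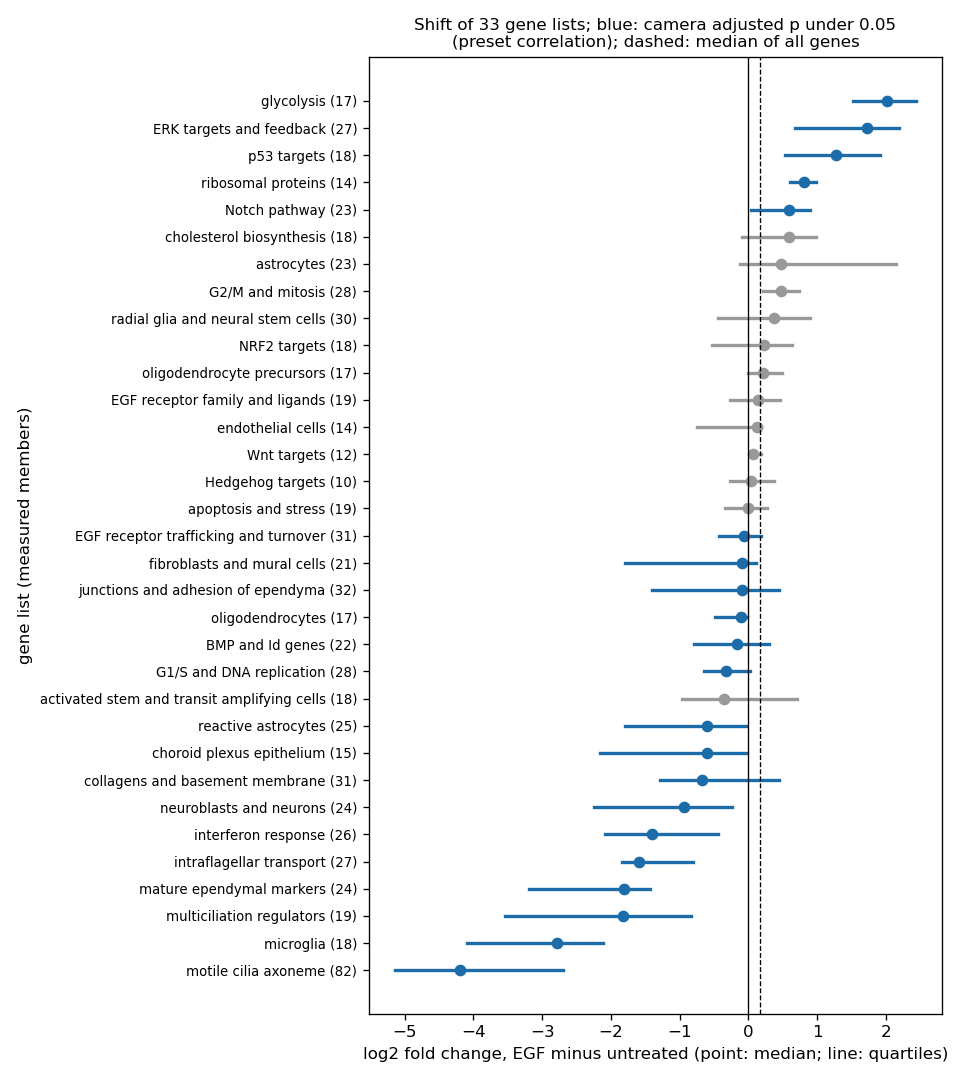
Log2 fold change, EGF minus untreated (horizontal axis), of the 33 gene lists (vertical axis, measured members in brackets); points are medians, lines run between the quartiles, blue marks lists that passed with the preset correlation, and the dashed line is the median of all genes, 0.17. The motile cilia axoneme lies lowest at -4.20 and glycolysis highest at 2.01; no list passed with an estimated correlation.

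The authors' deposited table compares groups headed ctrl and gf and lists 4136 clusters, 1565 higher and 2571 lower in gf. Its group means are not those of the 8 arrays: 83.9% of the ctrl means in the authors' deposited table lie outside the range of the 4 untreated arrays and 82.1% of the gf means outside that of the 4 EGF arrays, with a tolerance of 0.01. Which arrays entered the authors' deposited table is not stated in the sources used here. Across clusters, which are not independent replicates, its differences and those of the arrays had r = 0.740, and 85.0% had the same sign. Of 2721 listed clusters that stand for a tested gene, 2327 were called here with the sign of the authors' deposited table, 149 with the opposite sign and 245 were not called. Among all genes tested here 60.3% were called. In the other direction, 1709 of the 4203 genes changed at least 2-fold here were in the authors' deposited table, 1669 with the same sign. All 78 motile cilia genes and all 14 microglial genes in the authors' deposited table were lower in gf, and 19 of 20 ERK genes were higher. Other lists went the other way: 15 of 16 collagen and basement membrane genes and 5 of 6 neuroblast and neuron genes listed in the authors' deposited table were higher in gf. Stmn2 was higher in gf by 2.31 in the authors' deposited table (false discovery rate 0.0074) and fell by 4.81 here. Ntsr2 differed by -1.94 there, with a false discovery rate of 0.152, and rose by 6.18 here. Of the 4136 clusters, 3295 had a false discovery rate under 0.05 in the authors' deposited table.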

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

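The tests of the scaling and of the intervals between cell type lists were chosen only after the results were seen; the other tests in this part were fixed before.

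Across 378 groups of 4 values (array medians, component scores, list means and named genes), 21 held an array far from the other 3 relative to the group's range (5.56%), where chance gives about 1 in 20. Among untreated arrays, replicate 1 stood apart for Dlx6os1 (8.68), Nrarp (7.11), Me1 (13.06) and Numb (8.40), and replicate 2 for Stmn2 (11.94), Eng (6.84), Egr1 (7.84) and Cdkn1a (14.49). Untreated replicate 3 stood apart for Dynlrb2 (12.71), and replicate 4 for Id4 (11.75), Kdr (6.21), Gli3 (9.01) and Hhip (5.73). Among EGF arrays, replicate 1 stood apart for Itgam (6.20), Ccne2 (7.17) and Hmmr (12.61), and replicate 2 for Sox8 (12.27), Tspan2 (8.34) and the mean of the radial glia and stem cell list (11.46). EGF replicate 3 stood apart for Thbs1 (8.60) and Cdkn1a (16.44). Clusters with no gene name or several, which the tests of genes and lists left out, also differed between the groups: 1468 of 34664 changed at least 2-fold. The count was 0 in any other split of the arrays, but those splits mix the groups, which widens their residual spread.

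The 18549 changed genes were reached by 1 of the 35 splits of the 8 arrays into 4 and 4, the real one. The highest count of any other split was 0 (limma, up to 2892 genes at an unadjusted p under 0.05). Every other split mixes the groups, which widens its residual spread, and 1 of 35 is the smallest share possible. The splits argue against a chance arrangement of these arrays. A chance difference between cultures stays open, since the replicates may be technical. The same reading and limit hold for the 4203 genes changed at least 2-fold (highest other 0). The 21 lists were also reached by 1 of 35 splits. Splits that exchange a single array, and so keep part of the grouping, called up to 20 lists. That lead is too small to argue against chance for the list calls. Whether the treatment was EGF, or MLN4924 as the source names say, cannot be told apart. Both readouts missed the values set before for MLN4924 as the cause. For the ERK targets that was a median of 0.2 or less (1.73, interval 1.09 to 2.06). For the NRF2 targets it was at least 0.58 (0.22, interval -0.44 to 0.54). The medians also met the rule set before against MLN4924. That rule asked for an ERK median above 0.3 with a camera adjusted p under 0.05 (1.2e-05). It also asked for an NRF2 median under 0.3. The NRF2 targets went both ways, however (8 rose, 7 fell). Their interval reaches past 0.3, a limit the rule did not set, so the label stays unsettled. Hypoxia-inducible genes also depend on a cullin ligase, which MLN4924 blocks, so their rise leaves both labels open. Whether either label accounts for the rise of p53 targets was not tested.

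The fall of motile cilia genes (median -4.20) might come from the scaling between arrays, but the median nearest to 0 under 3 other scalings was -4.26, which argues against that. A lower share of ependymal cells that raises every other type alike is argued against by microglia (interval -3.88 to -2.16) and astrocytes (interval 0.27 to 0.72), which moved apart by 2.43 on the log2 scale beyond their intervals. Those intervals come from draws of list members, so they measure the spread between genes and not between cultures. The test fixed before against replacement by other cells, lists called in opposite directions, depended on the scaling: microglia and neuroblasts were called lower under each scaling, while the astrocyte list had adjusted p = 0.0980 with the deposited values and passed after 3 other scalings (adjusted p = 0.0447, 0.0131 and 0.0111), though no list passed with an estimated correlation. A replacement by cells with higher levels of many astrocyte markers (17 of 23 rose, 6 fell) and fewer microglia and neuroblasts, and a lower expression of cilia genes within cells, therefore both stay open. RNA integrity was not tested.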

How the results depend on the processing

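The list of hypoxia-inducible genes, with its scalings, was chosen after seeing the data, and the other alternatives in this part before. The count of changed genes stayed within 1.5 times the main count under all 18 alternatives and that of genes changed at least 2-fold under all 17. Among the 17 is treat, which tests for changes beyond 1.5-fold and so is not a like count. It called 5190 genes, among them 4158 of the main 2-fold calls. Like counts did not hold the same genes. Of the 18549 main calls, 13543 were called in either direction after quantile normalization, 12092 after centring and 12677 after cyclic loess. Of the 4203 main calls of at least 2-fold, 3976, 3629 and 3805 were kept. Without 1 array the count of changed genes ranged from 16428 to 18750 and that of genes changed at least 2-fold from 4126 to 4255. Of 154 named genes 152 kept their direction and call under the 16 alternatives run on single genes, which leave out treat and the adjusted p under 0.01, and 0 reversed; Ttr lost its call after quantile normalization (adjusted p = 0.0574) and under the block, and without untreated replicate 1 or 2 or EGF replicate 1, 2 or 3, and Wif1 under 3 scalings, with no value among brighter clusters. With the replicate block 17437 genes changed and 4202 at least 2-fold, and the G2/M list passed (median 0.48, adjusted p = 0.0192). Same-numbered arrays did not deviate together (correlations from -0.084 to -0.003, and 0 arrays closest to their own number), so the numbers were not taken to pair the samples. All 21 list calls were lost with an estimated correlation, among them those of the multiciliation (-1.82), cilia (-4.20), mature ependymal (-1.80), G1/S (-0.32), ERK (1.73) and EGF receptor trafficking (-0.063) lists. The astrocyte list passed after quantile normalization (0.28), centring (0.30), cyclic loess (0.36) and with fry (0.48), and the G2/M list likewise (0.38, 0.29, 0.36, 0.48) and against random lists (0.48); the radial glia list passed with fry (0.38) and the activated stem cell list against random lists (-0.36). The trafficking list lost its call after quantile normalization (-0.075), cyclic loess (-0.20), with brighter clusters alone (-0.063) and against random lists (-0.063), and G1/S against random lists (-0.32). Without 1 array the G2/M median ranged from 0.39 to 0.54, passing without untreated replicate 1 or EGF replicate 2, and the trafficking median from -0.10 to -0.031, failing without EGF replicate 1. The test direction turned, with no call in camera either way, for EGF receptor family genes after quantile normalization (0.045), centring (-0.053), cyclic loess (-0.062) and with brighter clusters (0.13), and for NRF2 targets (0.0061, 0.036, 0.059 and 0.12). It also turned with fry for both (0.14 and 0.22) and for apoptosis and stress genes (-0.0075), and against random lists for EGF receptor family (0.14) and NRF2 (0.22) genes. The cause of these changes was not tested. No background estimate was used here, so what dim signals limit is unknown beyond the excess of small rises among dim genes given above.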

Other observations

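The tests in this part were chosen after other hypoxia-inducible genes had been seen among the largest rises, but before the values of the genes tested were seen. A list of 30 genes known to be induced under low oxygen, none in an earlier list, had 29 measured members, of which 24 rose, 2 fell and 3 did not pass (median 2.37, interval 1.52 to 2.62). Car9 rose from 8.11 ± 0.26 to 12.21 ± 0.23 (n = 4), Stc2 by 4.07 ± 0.09 (SE), Bnip3 by 4.04 ± 0.19 and the oxygen sensor gene Egln3 by 2.51 ± 0.15, while Angptl4, another known target, fell by 4.94 ± 0.15 and Ndrg1 and Plod2 differed by 0.12 each. These genes were named after their values were seen.

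Hypoxia-inducible factor activity is a candidate explanation: the median lay 2.21 above that of all genes, with a camera p = 9.0e-10 at the preset correlation and p = 0.0546 with an estimated correlation. The scaling between arrays is argued against by the lowest median under 3 other scalings, 2.19. What would raise the factor stays open, since no oxygen level is given in the labels, growth factor signalling can raise it, and MLN4924, named in the source names, blocks the ligase that degrades it. As a hypothesis found and tested on the same arrays, it needs other cultures.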
